A study of Mus musculus with 20 samples.

How the data were processed

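The deposited material was 1 table of read counts per gene for 20 libraries of poly(A)-enriched RNA from BV-2 cells, wild type or labelled as RGS10 knockout, with vehicle or IFNγ for 48 h. Per the labels, each of the 4 groups had 5 biological replicates, of which replicates 1 to 3 were batch 1, replicate 4 batch 2 and replicate 5 batch 3. The counts are raw counts as deposited: the authors' processing notes name FastQC, Trim Galore, STAR, DESeq2 and the mouse genome build GRCm39, without versions. The tool that counted reads, the strand setting and the annotation release are not given in the sources used here, so reads from overlapping genes on opposite strands, or from paralogs, may have been assigned either way. All 20 count columns matched a library, and no column was without one. The table held 56941 Ensembl gene IDs, of which 28314 had no read in any library. GENCODE vM21 on GRCm38 gave symbols for 51948 IDs (91.2%) and gene order. The 4993 IDs without a symbol held 0.482% of counts and stayed in the tests. No coordinate was used, and the neighbour measures below rest on GRCm38 gene order, not on the build of the counts.

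Library sizes were scaled by TMM in edgeR 4.0.16 (R 4.3.3, limma 3.58.1), and genes were filtered with filterByExpr over the 4 groups, which left 13755 genes, 13439 of them with a symbol. Negative binomial quasi-likelihood models with robust dispersion took group and batch as terms and left 14 residual degrees of freedom. The 5 comparisons were IFNγ against vehicle in each line, knockout against wild type under each treatment, and the difference of the IFNγ responses (knockout minus wild type). Genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison were called, and "rose", "fell", "higher" and "lower" refer to calls. Log2 changes are given ± SE and levels as CPM on TMM-scaled library sizes, as mean ± SD of 5 libraries. Malat1, Neat1 and Xist, used as signs of library quality, are given as CPM on plain library totals. A fold against a group without any read was computed from the CPM against a floor of 3 counts over the group and is given as a lower bound. Single values such as Rgs10 were also compared with an exact permutation test over the 252 splits of 5 against 5, whose smallest two-sided p is 0.0079.

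Libraries with the same number were checked for pairing across groups. Deviations from the group mean within batch 1 correlated at −0.04 to 0.04 between same-number libraries, so the numbers were not taken as pairs beyond the batch. No replicates were copies of each other: the chi-squared per degree of freedom between replicates was 3.69 to 14.4 within batch 1 and 15.2 to 397 across batches. With 5 libraries per group the precision was tested on simulated data with the dispersion and depth of these libraries. Of genes planted at 1.5-fold, 2-fold and 4-fold, edgeR called 28.4%, 68.7% and 97.0%, and it called 0.077% of unchanged genes. DESeq2 1.42.0 called 37.3%, 79.1% and 97.0% of the planted genes and limma-voom 28.4%, 68.7% and 95.5%. With 67, 67 and 66 genes planted, these rates need not carry over to comparisons with 894 to 8101 calls.

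There were 36 gene lists, written before the data were examined, covering interferon response, antigen presentation, inflammation, motility, G protein signalling, metabolism, cell cycle, microglial identity, other cell types and RNA quality. Lists with at least 5 tested genes (31) were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. An estimated correlation and the rotation test fry were run beside it. List counts are given over all tested genes and, for most lists, also adjusted over the list alone. In simulated data, where genes were drawn independently, a list planted at 1.5-fold was called and no other list was. Members of real lists correlate, at an estimated 0.73 for ribosomal protein genes with IFNγ in wild-type cells. The simulation thus says nothing about false list calls in these libraries.

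Genes to name were chosen by a rule: a fixed panel, the 8 genes with the largest called change each way, and members of every list. The 8 genes needed 1 CPM or more in either group and the same sign in all 5 same-numbered sets of libraries. From each list the rule took up to 2 called members each way with the smallest p. If no member was called, the rule took the one with the highest mean CPM. It gave 137, 132, 133, 135 and 102 genes for the 5 comparisons. The text names 60, 63, 78, 64 and 50 of them, a choice made after the values were seen, and the genes left out were less stable. Some genes, 1 of the panel among them, and 1 gene list are not reported here. Over all genes of the rule, 113 of 135, 104 of 129, 54 of 120, 68 of 125 and 4 of 83 calls held in every alternative setting.

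Alternatives chosen before the data were examined were RLE size factors, no filter beyond 1 read, DESeq2, limma-voom, no batch term (16 residual degrees of freedom), replicate number as a block, batch 1 alone, batches 2 and 3 alone, only the groups compared, each library left out in turn, an adjusted p under 0.01, and a change of at least 1 log2. Chosen after seeing the data were treatment-specific batch terms, plain library totals, batches 1 and 3 alone, and removal of a shift shared by neighbouring genes. For the last, tested genes were put in GRCm38 gene order, and the neighbour distance of 50 genes, the blocks of 50 genes and the limit of 0.3 log2 were chosen after exploratory looks at the same data. A planted shift of 0.58 log2 over 200 neighbouring genes gave a fitted shift of 0.58 log2 inside and a median absolute shift of 0.0186 log2 outside. Gene order was shuffled 1000 times for comparison. For each comparison 100 of the 126 splits of 10 units into 5 and 5 were drawn with a fixed seed, the real one included. All 40 splits that exchange units only within a batch were run as well, a choice made after the results were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Raw reads were not used here.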

Results

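Gene expression was measured by poly(A)-selected RNA sequencing in BV-2 cells, an immortalized mouse microglial line, and in a derivative labelled as lacking RGS10. RGS10 belongs to the regulators of G protein signalling, which speed up GTP hydrolysis by the alpha subunits of heterotrimeric G proteins, and the series title ties it to the migration of these cells. Both lines were kept for 48 h in medium alone (vehicle) or with 10 ng/mL of interferon gamma (IFNγ), the cytokine that drives macrophage and microglial activation. Each of the 4 groups held 5 libraries, 20 in all, of which 3 replicates came from batch 1 and 1 each from batches 2 and 3. Total counts per library ran from 15866749 to 29157740. Wild-type vehicle libraries, at 15866749 to 21585759, were on average the shallowest group. At this depth 3 counts over the wild-type vehicle group amounted to 0.0308 CPM. The first 3 principal components of log2 CPM held 43.4%, 23.6% and 10.3% of the variance. Libraries of different batches lay further apart than replicates of batch 1. The biological coefficient of variation was 5.89% within batch 1 and 24.2% over all libraries with a batch term. The labels call the replicates biological but give no culture history, so p-values measure the spread between these samples, which rests in effect on 3 batches.

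Rgs10 itself (ENSMUSG00000030844) was read in every library, the knockout ones included. Under vehicle it stood at 63.0 ± 6.6 CPM in wild-type and 28.2 ± 4.6 CPM in knockout cells (mean ± SD, n = 5 each), so that knockout libraries kept 44.8% of the wild-type level. The fitted difference was −1.17 ± 0.17 log2 (edgeR adjusted p = 3.2e-05), and every knockout library lay below every wild-type one (two-sided exact permutation p = 0.0079, the smallest that 5 against 5 can give). Within batches 1, 2 and 3 the difference was −1.09, −1.08 and −1.47 log2. IFNγ lowered Rgs10 in wild-type cells to 29.6 ± 11.7 CPM, a change of −1.17 log2 (edgeR adjusted p = 1.0e-05, exact permutation p = 0.0079). Knockout cells under IFNγ held 24.4 ± 14.7 CPM, which differed from wild-type cells under IFNγ by −0.33 log2 (edgeR adjusted p = 0.13, exact permutation p = 0.46) and from knockout cells under vehicle by −0.33 log2 (edgeR adjusted p = 0.12, exact permutation p = 0.65). The fall with IFNγ in knockout cells passed in 6 of 22 alternative settings, given below. By batch, the knockout difference under IFNγ was −0.31, 0.02 and −0.89 log2. The batch 2 libraries held the highest Rgs10 level of both IFNγ groups, 49.97 CPM in wild-type and 50.52 CPM in knockout cells. The difference under IFNγ passed the test in batch 1 alone (−0.28 log2) and without the knockout library of batch 2 (−0.56 log2). Counts per gene do not show which part of a transcript the reads came from, so a disrupted transcript and an intact one could not be told apart here.

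**Figure D1:**
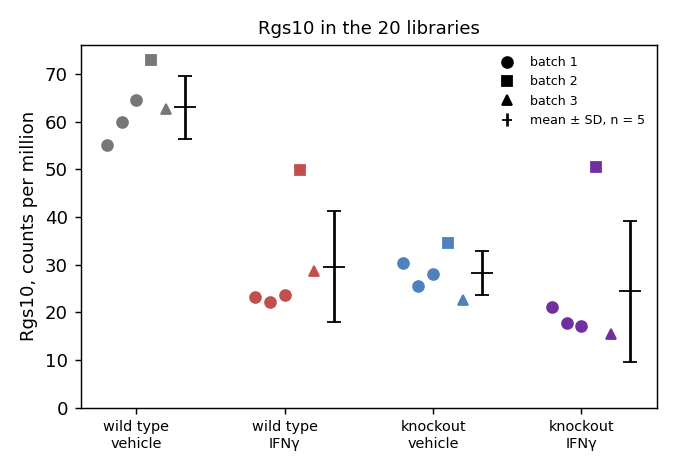
Rgs10 CPM on TMM-scaled library sizes (vertical axis) in the 20 libraries of the 4 groups (horizontal axis); circles, squares and triangles are batches 1, 2 and 3, and bars give the mean ± SD of 5 libraries. Under vehicle the knockout libraries (mean 28.2) lay below the wild-type ones (mean 63.0), whereas under IFNγ the groups overlapped and both batch 2 libraries stood at 49.97 and 50.52 CPM.

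The response of wild-type cells to IFNγ asks what the cytokine does to the parental line. Interferon-inducible GTPases and most antigen presentation genes, chemokines and inflammatory mediators rose, and most genes of S phase and mitosis, of cholesterol synthesis and of ribosomal proteins fell. Each of these lists passed an exact permutation test of list means (adjusted p = 0.012), but only GTPases passed camera with an estimated correlation (0.017). All 21 lists that passed the permutation test shared its smallest possible p of 0.0079, so it cannot grade single lists. Of 13755 genes tested, 8101 differed, 3986 higher and 4115 lower, and 2270 and 1873 of these by more than 1 log2. Clec9a, a C-type lectin of dendritic cells, and Ubd, a ubiquitin-like modifier, had no read in any wild-type vehicle library and were at least 785-fold and at least 531-fold higher with IFNγ, against a floor of 3 counts over the group. Gbp2 went from 7.95 ± 5.07 to 7438 ± 5241 CPM (SD, n = 5), a fitted rise of 918-fold. Other large rises were those of the collagenase Mmp13 (1724-fold), the uridine phosphorylase Upp1 (1213-fold), the GTPases Tgtp1 (1012-fold) and Gbp10 (799-fold) and the chemokine Ccl8 (941-fold). At the other end, the fractalkine receptor Cx3cr1 fell from 86.1 ± 37.5 to 1.03 ± 0.50 CPM (82.4-fold), and Gdpd2, the coagulation factor subunit F13a1 and the carbonyl reductase Cbr2 fell 205-fold, 111-fold and 68.3-fold. Adjusted p of the genes in this paragraph lay between 6.8e-14 (Upp1) and 2.7e-07 (Gdpd2) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

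All 18 measured GTPases of the GBP and IRG families rose in wild-type cells, over all genes and adjusted over the list alone, with a median of 5.34 log2 and Gbp6 at 38.0-fold (camera adjusted p = 2.5e-33, and adjusted p = 0.017 with an estimated correlation). Members of these families share sequence, so the split of reads between them is uncertain. JAK-STAT and IRF genes rose in 15 of 21 and fell in 2 (16 and 2 adjusted over the list alone), among them the transcription factor Irf1 (33.1-fold) and, as a fall, the receptor chain Ifngr1 (1.69-fold). Of 24 MHC class I and immunoproteasome genes 23 rose and 1 fell (the same adjusted over the list alone), with H2-T23 at 13.5-fold and the tapasin-like Tapbpl at 16.3-fold. Of 13 MHC class II genes 8 rose and none fell (9 and none adjusted over the list alone), led by H2-Ab1 (117-fold) and the class II transactivator Ciita (63.9-fold), with the invariant chain Cd74 at 11.98-fold. Chemokine ligands rose in 13 of 18 and fell in 1 (the same adjusted over the list alone). Cxcl9 rose 740-fold, Ccl2 9.10-fold, Ccl5 7.64-fold and Cxcl10 2.53-fold, while Ccl9 fell 3.01-fold. Among 30 inflammatory mediators 24 rose and 2 fell (the same adjusted over the list alone). The inducible nitric oxide synthase Nos2 rose 138-fold, the cyclooxygenase Ptgs2 104-fold, the checkpoint ligand Cd274 153-fold, Tnf 12.8-fold, Il6 5.30-fold and Il1b 2.40-fold, and the constitutive cyclooxygenase Ptgs1 fell 5.67-fold. These 5 lists passed camera with adjusted p from 8.8e-18 to 4.1e-06, which with an estimated correlation became adjusted p = 0.16 for JAK-STAT and IRF, MHC class II and chemokine genes and 0.10 for MHC class I genes and inflammatory mediators.

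Motility and surface genes moved in both directions in wild-type cells. Adhesion genes rose in 21 of 34 and fell in 5 (22 and 6 adjusted over the list alone), with the scavenger receptor Cd36 (10.3-fold) and the galectin Lgals3 (6.97-fold) higher and the integrin Itga4 6.11-fold lower. Matrix proteins and proteases rose in 18 of 25 and fell in 2 (19 and 2 adjusted over the list alone), the urokinase receptor Plaur by 23.2-fold. Phagocytosis and complement genes rose in 19 of 26 and fell in 2 (the same adjusted over the list alone), the Fc receptor Fcgr4 by 13.7-fold, while the mannose receptor Mrc1 fell 9.33-fold. Disease-associated microglia markers rose in 15 of 24 and fell in 3 (the same adjusted over the list alone), with the lectin Clec7a at 24.4-fold. Macrophage identity genes rose in 14 of 23 and fell in 2 (the same adjusted over the list alone), including Itgam at 2.34-fold, and the calcium-binding protein Aif1, an actin regulator, rose 4.86-fold. With an estimated correlation adjusted p was 0.37 for adhesion, disease-associated and identity genes, 0.34 for phagocytosis and 0.16 for matrix genes, against 0.0029 or less with the preset value. The small GTPase Rhoc was 5.04-fold higher and the Rac exchange factor Arhgef6 6.19-fold lower. Among lists that camera did not call, RGS family members other than Rgs10 rose in 4 and fell in 3 of 12, Rgs1 by 78.9-fold upwards. Toll-like receptor and NF-κB genes rose in 13 and fell in 8 of 28, with Tlr2 6.77-fold lower. Cxcr4, the receptor of Cxcl12, was 1.51-fold higher and the purinergic receptor P2ry12 2.90-fold lower. The calcium sensor Stim2 stood at −0.14 ± 0.14 log2 (adjusted p = 0.39).

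S phase and mitosis genes fell in 36 of 42 and rose in 1 (the same adjusted over the list alone), with a median of −1.85 log2 overall and −1.50, −2.85 and −3.12 in batches 1, 2 and 3. Signs of RNA quality moved with IFNγ and batch as well: the nuclear RNA Malat1 stood at 1514 and 955 CPM in the wild-type IFNγ libraries of batches 2 and 3, at 355 to 386 CPM in those of batch 1 and at 64.4 to 166 CPM under vehicle, TMM factors were 0.63 and 0.76 against 1.04 to 1.05 in batch 1, and the 10 largest genes held 17.1% and 14.7% of counts against 7.60% to 7.86%. The mitotic kinase Aurka dropped from 97.6 ± 33.2 to 16.9 ± 6.0 CPM (5.79-fold) and the checkpoint gene Bub1b fell 3.50-fold. Of 19 p53 targets 11 rose and 2 fell (13 and 2 adjusted over the list alone), with Mdm2, which degrades p53, 4.04-fold higher and Trp53 2.41-fold lower. Cholesterol synthesis genes fell in 18 of 22 and none rose (the same adjusted over the list alone), the thiolase Acat2 by 9.44-fold and the demethylase Cyp51 by 4.61-fold, and the lipid desaturase Scd2 fell 11.3-fold. NRF2 and antioxidant genes rose in 13 of 25 and fell in 3 (the same adjusted over the list alone), haem oxygenase Hmox1 by 6.43-fold. Respiratory chain subunits fell in 18 of 36 and rose in 1 (17 and 1 adjusted over the list alone; adjusted p = 0.021, and 0.71 with an estimated correlation), with a median of −0.31 log2. Of 29 ribosomal protein genes, a list kept for RNA quality, 26 fell and none rose (the same adjusted over the list alone), Rps4x by 2.69-fold. Adjusted p with an estimated correlation was 0.19 for cell cycle, 0.28 for cholesterol synthesis, 0.16 for p53 and NRF2 and 0.34 for ribosomal protein genes, against 0.0195 or less with the preset value. Other lists kept for RNA quality were not called. Mitochondrially encoded genes rose in 2 of 10 (1 adjusted over the list alone; camera adjusted p = 0.56), mt-Co1 by 2.55-fold, with list medians of 0.94, −0.96 and 0.86 log2 by batch. Replication-dependent histone transcripts, which carry no poly(A) tail, rose in 4 of 5 (the same adjusted over the list alone; camera adjusted p = 0.11), Hist1h2bc by 3.92-fold. Of the 59 named genes past the threshold, 53 kept their call in all 22 alternative settings. The calls of Cxcr4, Il1b, mt-Co1, Cxcl10, Il6 and Rgs10 were lost in 7, 11, 2, 1, 1 and 1 settings, and Cxcr4 turned to −0.12 log2 in batches 2 and 3. Sizes of some large changes depended on the setting, with Cxcl9 between 7.15 and 15.92 log2, Gbp2 between 8.45 and 12.21, Clec9a between 9.48 and 12.51, Tgtp1 between 9.09 and 12.08, Gdpd2 between −8.94 and −6.10 and F13a1 between −8.52 and −5.82. With plain library totals the median of all genes lay at −0.21 log2 and 36.7% of calls were rises, against 49.2%, so directions are relative to TMM scaling.

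In knockout cells the same comparison asks how the line labelled as knockout answers IFNγ. GTPases and many antigen presentation genes and chemokines rose here too, and 22 of 42 cell cycle, 19 of 36 respiratory chain and 14 of 22 cholesterol synthesis genes fell. With an estimated correlation GTPases and MHC class I genes passed, but class II genes (adjusted p = 0.097), chemokines (0.082), cholesterol synthesis (0.55), respiratory chain (0.58) and cell cycle genes (0.58) did not, and the last also failed an exact permutation test of list means (adjusted p = 0.112). The test called 5937 genes, 2937 higher and 3000 lower, with 1489 and 831 past 1 log2. Clec9a, the class II genes H2-Aa and H2-Eb1, the GTPase Gbp10 and Ccl8 had no read in knockout vehicle libraries. They were at least 1652-fold, 1228-fold, 1211-fold, 1591-fold and 935-fold higher with IFNγ. Cxcl9 and the chemokine Ccl22 rose 5194-fold and 2995-fold from levels near 0. Falls were led by the inhibitory receptor Cd101 (83.7-fold), the secreted glycoprotein Olfm4 (77.1-fold), the receptor Cd300e (47.8-fold), Cx3cr1 (26.6-fold, from 70.7 ± 14.7 to 2.90 ± 1.98 CPM) and F13a1 (26.4-fold). Adjusted p in edgeR's quasi-likelihood test was 0.00011 or less for each of these genes.

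All 18 GTPases rose in knockout cells, over all genes and adjusted over the list alone, with a median of 5.17 log2, Tgtp1 at 724-fold and Gbp6 at 56.7-fold. JAK-STAT and IRF genes rose in 15 of 21 and fell in 2 (15 and 3 adjusted over the list alone), with the AP-1 factor Batf2 at 153-fold and Irf1 at 25.7-fold. MHC class I genes rose in 22 of 24 and fell in 1 (23 and 1 adjusted over the list alone), H2-T23 by 12.01-fold and H2-M3 by 3.56-fold. Of 30 inflammatory mediators 25 rose and 1 fell (the same adjusted over the list alone). Nos2 rose 174-fold, Cd274 49.7-fold, Ptgs2 41.3-fold, Tnf 15.2-fold, Il6 10.3-fold and Il1b 3.01-fold, and Ptgs1 fell 10.7-fold. These 4 lists also passed with an estimated correlation, at adjusted p = 0.00053 for GTPases, 0.048 for JAK-STAT and IRF genes, 0.0070 for MHC class I genes and 0.0058 for inflammatory mediators. Class II genes rose in 8 of 13 and none fell (the same adjusted over the list alone), with H2-Ab1 at 1026-fold, Ciita at 253-fold and Cd74 at 3.50-fold. Chemokines rose in 13 of 18 and fell in 1 (the same adjusted over the list alone), Ccl2 by 19.5-fold, Ccl5 by 9.77-fold and Cxcl10 by 3.63-fold, against a 6.93-fold fall of Ccl9. Interferon-stimulated antiviral genes rose in 19 of 31 and fell in 2 (21 and 2 adjusted over the list alone), with the membrane protein Ifitm3 at 12.1-fold and the nucleic acid sensor Zbp1 at 21.4-fold. With an estimated correlation their adjusted p was 0.097 for class II genes, 0.082 for chemokines and 0.18 for antiviral genes.

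Phagocytosis and complement genes rose in 20 of 26 and fell in 1 (the same adjusted over the list alone), Cd36 by 30.99-fold and Fcgr4 by 10.04-fold, with Mrc1 3.61-fold lower. Adhesion genes rose in 19 of 34 and fell in 5 (the same adjusted over the list alone), and matrix genes rose in 15 of 25 and fell in 2 (16 and 2 adjusted over the list alone), with Mmp13 at 184-fold and Plaur at 13.5-fold. Macrophage identity genes rose in 14 of 23 and fell in 1 (the same adjusted over the list alone), with the transcription factor Irf8 at 15.5-fold, lysozyme Lyz2 at 3.00-fold and Itgam at 1.54-fold. Disease-associated markers rose in 16 of 24 and fell in 3 (the same adjusted over the list alone). With an estimated correlation adjusted p was 0.082 for phagocytosis, 0.20 for adhesion, 0.097 for matrix, 0.39 for identity and 0.46 for disease-associated genes. Homeostatic microglia markers split into 5 that rose and 4 that fell of 16, with the phagocytic kinase Mertk 5.73-fold higher and the transcription factor Mef2c 3.72-fold lower. Of 30 chemoattractant receptors 11 rose and 9 fell, with Ccr1 15.2-fold higher and the sphingosine-1-phosphate receptor S1pr1 5.18-fold lower. Aif1 rose 16.1-fold, the Ena/VASP protein Evl 14.3-fold and Rgs1 16.5-fold, and Arhgef6 fell 3.08-fold. Cxcr4 was 1.49-fold lower, P2ry12 stood at 0.01 ± 0.29 log2 (adjusted p = 0.99) and Stim2 at −0.16 ± 0.14 log2 (adjusted p = 0.39).

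Cell cycle genes fell in 22 of 42 and rose in 1 in knockout cells (25 and 2 adjusted over the list alone), with a median of −0.76 log2 overall and −0.38, −0.93 and −1.58 in batches 1, 2 and 3. Aurka fell 1.66-fold and Bub1b 1.94-fold. Cholesterol synthesis genes fell in 14 of 22 and none rose (the same adjusted over the list alone), Acat2 by 3.17-fold and the epoxidase Sqle by 1.88-fold. Respiratory chain subunits fell in 19 of 36 and none rose (the same adjusted over the list alone). Of 19 p53 targets 11 rose and 2 fell (12 and 2 adjusted over the list alone), Mdm2 3.37-fold higher and Trp53 1.99-fold lower, and of 25 NRF2 genes 11 rose and 3 fell (the same adjusted over the list alone), with the glutathione synthesis subunit Gclm at 4.17-fold and Hmox1 at 2.79-fold. Ribosomal protein genes fell in 19 of 29 and none rose (22 adjusted over the list alone), Rps4x by 1.71-fold. The estimated correlation gave an adjusted p of 0.58 for cell cycle, respiratory chain and ribosomal protein genes, 0.55 for cholesterol synthesis, 0.13 for p53 and 0.11 for NRF2 genes. Calls of 57 of the 60 named genes past the threshold held in all 22 alternative settings. Cxcr4 lost its call in 8 settings, Il1b in 7, with −0.26 log2 in batch 1 alone, and Aurka in 1. Over the settings F13a1 ran from −8.69 to −3.35 log2, Olfm4 from −10.17 to −5.61, Ccl22 from 8.04 to 12.51, Cxcl9 from 10.59 to 13.87, H2-Aa from 10.32 to 13.37 and H2-Eb1 from 10.05 to 13.13. The nuclear RNA Malat1 stood at 1446 and 1004 CPM in the knockout IFNγ libraries of batches 2 and 3 and at 55.9 to 62.7 CPM in those of batch 1, and the 10 largest genes held 9.72% and 9.46% of counts against 4.81% to 4.92%.

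The 2 IFNγ responses shared no library. Both rose for 2441 genes, where independent lists would share 851, and both fell for 2593, where 897 would be shared, and 47 genes were called in opposite directions. Across the tested genes log2 changes correlated with a Pearson r of 0.82 and a Spearman coefficient of 0.82, a description over genes, which are not independent replicates. The correlation was 0.69 in batch 1 alone and 0.73 in batches 2 and 3.

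Knockout against wild-type cells under vehicle asks what differs between the lines before treatment. Knockout cells held less RNA of many complement and phagocytosis genes, of 9 of 18 chemokines, of several chemoattractant receptors and of the apolipoprotein Apoe, and more of a few cholesterol synthesis genes. None of the 13 lists called by camera passed with an estimated correlation. The test called 3753 genes, 1723 higher and 2030 lower, with 507 and 981 past 1 log2. The integrin subunit Itga9 (ENSMUSG00000039115) went from 19.5 ± 3.2 CPM to no read in any of 5 knockout libraries, at least 821-fold lower. Also without a read in the knockout line were Cth, a cystathionine lyase (at least 304-fold lower), the collagen Col5a3 (202-fold), H2-Aa (150-fold), the ephrin receptor Ephb2 (111-fold) and the homeobox gene Hoxb9 (97.9-fold, each at least). Olfm4 (280-fold), the organic cation exporter Slc47a1 (152-fold), the transcriptional coactivator Eya1 (134-fold) and the ubiquitin-conjugating enzyme Ube2e2 (121-fold) were higher in knockout cells, and the homeobox gene Barx2, without a read in wild-type vehicle libraries, was at least 40.3-fold higher. In edgeR's quasi-likelihood test these genes had adjusted p of 4.3e-05 or less and kept their call in every alternative setting.

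Of 26 phagocytosis and complement genes 16 were lower and none higher (19 and 1 adjusted over the list alone), with a median of −1.01 log2 overall and −0.98, −1.02 and −1.51 in batches 1, 2 and 3. The complement subunit C1qb stood at 470 ± 169 CPM in wild-type and 6.79 ± 4.37 CPM in knockout cells (71.4-fold lower), and Mrc1 was 10.7-fold lower. Disease-associated markers were lower in 10 of 24 and higher in 2 (11 and 2 adjusted over the list alone), Apoe going from 1872 ± 488 to 66.4 ± 17.3 CPM (28.2-fold) and the secreted phosphoprotein Spp1 8.79-fold lower. Homeostatic markers were lower in 8 of 16 and higher in 3 (8 and 4 adjusted over the list alone), with Fcrls 18.7-fold, Mertk 10.1-fold and P2ry12 3.75-fold lower, Gpr34 5.56-fold and Trem2 1.56-fold higher, and Cx3cr1 at −0.17 ± 0.31 log2 (adjusted p = 0.73). Chemokines were lower in 9 of 18 and higher in 1 (12 and 1 adjusted over the list alone), with Ccl24 382-fold, Ccl9 3.16-fold, Ccl5 1.86-fold and Ccl2 1.80-fold lower and Cxcl2 3.62-fold higher, while Cxcl10 stood at −0.28 ± 0.29 log2 (adjusted p = 0.51). Chemoattractant receptors were lower in 11 of 30 and higher in 2 (13 and 2 adjusted over the list alone), with the chemerin receptor Cmklr1 92.2-fold and the C5a receptor C5ar1 7.32-fold lower and S1pr1 2.07-fold higher, and Cxcr4 at −0.20 ± 0.21 log2 (adjusted p = 0.50). Inflammatory mediators were lower in 13 of 30 and higher in 1 (14 and 1 adjusted over the list alone), Il1a by 23.6-fold, Cd40 by 6.50-fold, Nos2 by 3.47-fold and Il1b by 3.40-fold, with Tnf at 0.14 ± 0.43, Il6 at 0.35 ± 0.80 and Ptgs2 at 0.16 ± 0.29 log2 and not past the test. By an estimated correlation the adjusted p was 0.22 for phagocytosis, 0.44 for disease-associated and 0.41 for the homeostatic, chemokine, receptor and inflammatory lists.

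MHC class II genes were lower in 6 of 13 and none higher (the same adjusted over the list alone), Ciita by 17.2-fold, with Cd74 at −0.52 ± 0.28 log2 (adjusted p = 0.17). JAK-STAT and IRF genes were lower in 7 of 21 and higher in 1 (the same adjusted over the list alone), Batf2 by 13.001-fold and Stat3 by 1.63-fold. Antiviral genes were lower in 6 of 31 and higher in 2 (9 and 2 adjusted over the list alone), Ifitm3 by 15.8-fold, with the sensor Ddx58 2.06-fold higher. Macrophage identity genes were lower in 8 of 23 and higher in 1 (9 and 1 adjusted over the list alone), the transcription factor Maf by 13.5-fold and Lyz2 by 4.16-fold, and Itgam stood at −0.14 ± 0.16 log2 (adjusted p = 0.56). Cholesterol synthesis genes were higher in 8 of 22 and none lower (the same adjusted over the list alone), the sterol carrier Stard4 by 14.3-fold. Stress response genes were higher in 11 of 29 and lower in 3 (the same adjusted over the list alone), Trib3 by 3.03-fold and Ppp1r15a by 2.46-fold. Among cholesterol efflux genes, which camera did not call, Abca1 was 1.65-fold higher and Nr1h3 2.05-fold lower. Adjusted p with an estimated correlation was 0.54 for class II, identity and cholesterol synthesis genes, 0.60 for JAK-STAT and IRF, 0.65 for antiviral and 0.41 for stress response genes.

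Among genes of cell movement and G protein signalling, adhesion genes were lower in 11 of 34 and higher in 4 (14 and 4 adjusted over the list alone; adjusted p = 0.0019, and 0.54 with an estimated correlation), with Cd36 9.93-fold lower and the adaptor Tln1 2.73-fold and the hyaluronan receptor Cd44 1.46-fold higher. Matrix proteases went both ways, with Mmp9 32.8-fold and the inhibitor Timp2 2.12-fold lower and the elastase Mmp12 10.3-fold higher. Of the small GTPases, Rhou was 7.27-fold lower, Rhoc 2.05-fold higher and Rac1 1.42-fold higher, and Aif1 was 7.24-fold lower. Other RGS members were higher in 7 of 12 and lower in 1 (the same adjusted over the list alone; camera adjusted p = 0.061), Rgs20 by 15.2-fold and Rgs18 by 4.09-fold. Of 27 G protein genes 4 were higher and 8 lower, among the latter the alpha subunit Gna15 (1.79-fold) and the receptor kinase Grk5 (2.31-fold). Grk5 is also 1 of 8 genes of a fixed list meant as neighbours of Rgs10, of which 3 were lower and none higher, Prdx3 by 1.40-fold. Their place next to Rgs10 in the mouse genome was not checked. Removing the shift shared by neighbouring genes ended the call of Prdx3 under vehicle but made Rgs10 pass under IFNγ. The list thus cannot be read as an effect near Rgs10. Store-operated calcium entry genes were higher in 2 and lower in 7 of 20 (3 and 7 adjusted over the list alone), with Orai1 1.41-fold and Stim1 1.29-fold higher, the potassium channel Kcnn4 2.497-fold lower and Stim2 at 0.11 ± 0.14 log2 (adjusted p = 0.62). In toll-like receptor signalling 2 of 28 genes were higher and 6 lower (4 and 7 adjusted over the list alone), the inhibitor Irak3 by 54.5-fold and the adaptor Myd88 by 2.08-fold. Markers of other cell types also differed between the lines at low to moderate levels. The neuronal Map2 and Slc17a7 were 7.53-fold and 39.5-fold lower and the lymphocyte kinase Lck 2.84-fold lower in knockout cells, and the endothelial receptor Kdr stood at 31.2 ± 5.5 CPM in wild-type and 319 ± 61 CPM in knockout cells (9.85-fold).

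The difference between the lines was shared by neighbouring genes. In GRCm38 gene order, the difference under vehicle of a gene and of the gene 50 places on correlated with a Spearman coefficient of 0.17 over 13423 genes, where the highest of 1000 shuffled orders gave 0.036, and the value for the wild-type IFNγ response was −0.0056. Of 259 blocks of 50 neighbouring tested genes, 52 were shifted by at least 0.3 log2 the same way under both treatments, 19 higher and 33 lower in the knockout line, where the highest of 1000 shuffles gave 1. Block medians under vehicle and IFNγ correlated with a Pearson r of 0.92. Blocks with the largest shifts under vehicle ran from Dctn3 to Anp32b (0.99 log2) and from Cda to Pdpn (−0.77 log2). Taking a shift shared by 50 neighbours out of the knockout libraries left 2379 genes called under vehicle, 1949 of them among the 3753. It ended the calls of Tln1, Cd44, Rac1, Abca1, Ddx58, Myd88, Ccl2, S1pr1, Stim1 and Prdx3 and of the JAK-STAT and IRF list, and turned Rac1 and Abca1 to −0.01 and −0.02 log2. Over all 23 settings Stim1, Ccl2 and Prdx3 lost theirs in 15, 10 and 7. Of the 69 named genes past the threshold 43 kept their call in all alternative settings, and batches 2 and 3 alone, with 1 library each, called 847 genes. Over the settings Map2 ran from −5.73 to −1.99 log2, Col5a3 from −10.56 to −7.02, H2-Aa from −10.29 to −6.76, Olfm4 from 6.92 to 10.44 and Cmklr1 from −9.13 to −5.82.

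**Figure D2:**
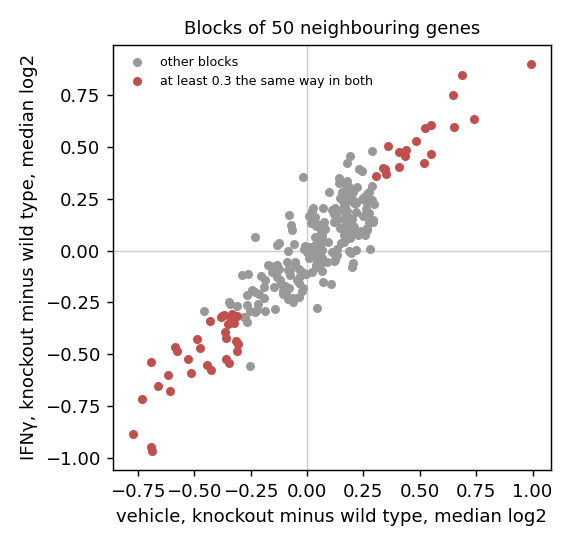
Median knockout minus wild-type difference, in log2, of 259 blocks of 50 neighbouring tested genes, under vehicle (horizontal axis) and under IFNγ (vertical axis); each point is 1 block, and red points are the 52 blocks shifted by at least 0.3 log2 the same way under both treatments. The blocks lie along a rising diagonal (Pearson r = 0.92), with the highest block at 0.99 log2 and the lowest at −0.77 log2 under vehicle.

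Knockout against wild-type cells under IFNγ asks what differs between the activated lines. Many mitosis and cholesterol synthesis genes were called higher and many MHC class II, phagocytosis, matrix and chemoattractant receptor genes lower in knockout cells. None of the 12 lists called by camera passed with an estimated correlation (adjusted p from 0.24), and cell cycle, class II and matrix genes did not pass an exact permutation test of list means (adjusted p = 0.131, 0.0757 and 0.0615), though each did when libraries were exchanged only within batches (0.0431), a test added after the results were seen. All 18 lists that passed the latter shared its smallest possible p of 0.025, so it cannot grade single lists. The test called 5363 genes, 2754 higher and 2609 lower, with 872 and 1247 past 1 log2. Largest among the lower genes were Ephb3, Acp5, an acid phosphatase, Afap1, an actin-binding adaptor, and Hoxb9, without a read in knockout IFNγ libraries and at least 186-fold, 132-fold, 122-fold and 122-fold lower, and Itga9 at 39.3 ± 13.8 against 0.0428 ± 0.0957 CPM (787-fold). Ube2e2 (518-fold), the immunoglobulin heavy chain Ighm (226-fold) and Slc47a1 (187-fold) were higher, and Eya1, without a read in wild-type IFNγ libraries, at least 40.3-fold higher. Adjusted p was 4.7e-06 or less for each in edgeR's quasi-likelihood test. Of the differences under vehicle, 1086 were also higher and 1321 also lower under IFNγ (345 and 385 for independent lists), and 60 had the opposite sign. The differences correlated across genes with a Pearson r of 0.76 and a Spearman coefficient of 0.61.

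S phase and mitosis genes were higher in 33 of 42 and lower in 1 (the same adjusted over the list alone), with a median of 1.18 log2 overall and 0.87, 1.92 and 2.18 in batches 1, 2 and 3, where TMM factors were 0.63 and 0.76 in the wild-type and 0.89 and 0.88 in the knockout IFNγ libraries of batches 2 and 3. In batch 1 Malat1 stood at 355 to 386 CPM in wild-type and 55.9 to 62.7 CPM in knockout IFNγ libraries. Mitochondrial genes held 0.56% to 0.67% and 0.17% to 0.19% of counts there. In batches 2 and 3 Malat1 was 1514 and 955 against 1446 and 1004 CPM, and mitochondrial shares were 0.48% and 0.51% against 1.20% and 0.58%. The share of RNA quality in the change was not tested. Aurka stood at 16.9 ± 6.0 CPM in wild-type and 90.7 ± 36.8 CPM in knockout cells (5.27-fold), and the spindle factor Tpx2 was 2.70-fold higher. Cholesterol synthesis genes were higher in 17 of 22 and none lower (18 and none adjusted over the list alone), Stard4 by 27.4-fold, and Scd2 was 4.60-fold higher. Ribosomal protein genes were higher in 19 of 29 and none lower (21 adjusted over the list alone), Rpl7 by 1.95-fold. Adjusted p with an estimated correlation was 0.32 for cell cycle and cholesterol synthesis and 0.65 for ribosomal protein genes. Class II genes were lower in 8 of 13 and none higher (9 and none adjusted over the list alone), Cd74 at 588 ± 281 against 3485 ± 3400 CPM (4.92-fold), Ciita 4.35-fold and the thiol reductase Ifi30 2.65-fold lower. Phagocytosis and complement genes were lower in 19 of 26 and higher in 1 (the same adjusted over the list alone), with the inhibitory Fc receptor Fcgr2b 5.27-fold and Mrc1 4.13-fold lower. Disease-associated markers were lower in 15 of 24 and higher in 1 (the same adjusted over the list alone), Apoe by 24.7-fold and Igf1 by 3.33-fold. Chemoattractant receptors were lower in 18 of 30 and higher in 4 (the same adjusted over the list alone), C5ar1 by 12.6-fold, Cmklr1 by 88.7-fold and Cxcr4 by 2.58-fold, with Cx3cr1 2.75-fold higher and P2ry12 at −0.37 ± 0.28 log2 (adjusted p = 0.33). For class II genes adjusted p with an estimated correlation was 0.42, and it was 0.32 for phagocytosis and disease-associated genes and 0.24 for receptors.

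Inflammatory mediators were lower in 16 of 30 and higher in 4 (the same adjusted over the list alone), Il1a by 21.3-fold, Cd80 by 4.80-fold, Nos2 by 2.75-fold, Il1b by 2.71-fold and Ptgs2 by 2.27-fold. Tnf stood at 0.38 ± 0.43 log2 (adjusted p = 0.51) and Il6 at 1.31 ± 0.69 log2 (adjusted p = 0.14). Chemokines were lower in 7 of 18 and none higher (the same adjusted over the list alone), Ccl8 by 8.31-fold and Ccl9 by 7.27-fold, while Ccl2, Ccl5 and Cxcl10 stood at 0.25 ± 0.30, −0.54 ± 0.25 and 0.23 ± 0.29 log2 and did not pass. Matrix genes were lower in 15 of 25 and higher in 1 (16 and 1 adjusted over the list alone), Mmp9 by 25.3-fold and Timp2 by 2.24-fold, and adhesion genes lower in 15 of 34 and higher in 6 (the same adjusted over the list alone), with Itga4 2.75-fold higher. Adhesion medians were −0.29, −1.01 and 0.01 log2 in batches 1, 2 and 3. The list lost its camera call without WT_IFNg replicate 4 and in batches 1 and 3 alone. Identity genes were lower in 12 of 23 and none higher (13 and none adjusted over the list alone), the transcription factor Cebpa by 3.32-fold, the lipopolysaccharide co-receptor Cd14 by 3.96-fold and Itgam by 1.67-fold. For these 5 lists adjusted p with an estimated correlation was 0.32 (inflammatory and matrix), 0.54 (chemokine and identity) and 0.65 (adhesion). In lists not called by camera, Gbp11 was 7.47-fold lower and Tgtp1 2.29-fold higher, and the kinases Jak2 and Jak1 were 2.72-fold and 2.19-fold lower. Rhou was 9.73-fold, Aif1 2.19-fold and Cdc42 1.62-fold lower, and the exchange factor Arhgef1 1.86-fold, Rac1 1.55-fold and Rgs14 2.01-fold higher. Grk5 and Kcnn4 were 1.97-fold and 2.60-fold lower and the calcium channel Orai3 1.87-fold higher, with Stim2 at 0.10 ± 0.14 log2 (adjusted p = 0.62). Hmox1 was 3.19-fold lower and Gclm 2.77-fold higher. Map2 was 11.3-fold and the mitochondrial mt-Cytb 3.76-fold lower and Kdr 3.58-fold higher. Calls of 40 of the 56 named genes past the threshold held in every alternative setting, though Itga9 ran from −12.74 to −8.91 log2 and Ube2e2 from 7.54 to 10.62. Cdc42 (0.09 log2), Rac1 and Rpl7 lost theirs with the neighbour shift removed, Il1b in 10 of 23 settings (−2.89 to −0.27 log2), and Cx3cr1 and mt-Cytb changed sign in batches 2 and 3 alone (−0.97 and 0.31 log2).

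**Figure D3:**
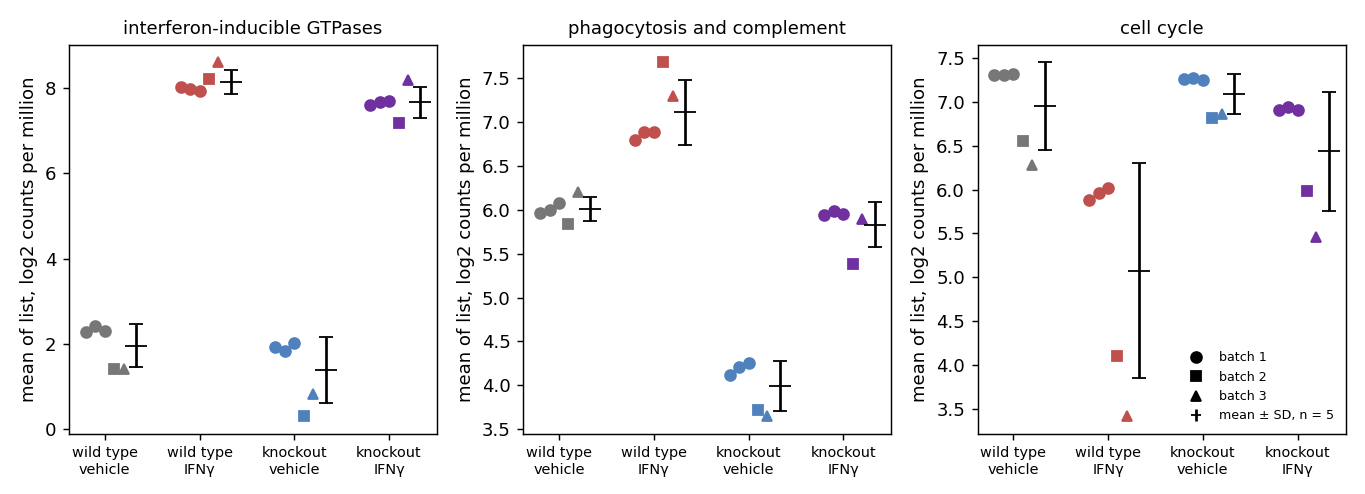
Mean log2 CPM of the members of 3 fixed gene lists (vertical axes) in each library of the 4 groups (horizontal axes); symbols are batches 1, 2 and 3, and bars give the mean ± SD of 5 libraries. Interferon-inducible GTPases rose with IFNγ in both lines, phagocytosis and complement genes were lower in the knockout line under both treatments, and cell cycle means changed with IFNγ by −1.88 log2 in wild-type and −0.65 log2 in knockout cells, a difference with an exact permutation adjusted p of 0.295.

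Whether the lines answer IFNγ differently was tested as the knockout response minus the wild-type response. Differences went both ways: some genes that were low in untreated knockout cells, such as Ifitm3, were induced there more steeply, and others, such as Olfm4 and Mmp12, had a more negative response. The test called 894 genes, 500 with a more positive and 394 with a more negative response in knockout cells, and 2955 had an unadjusted p under 0.05. Ifitm3 stood at 102 ± 44 and 94.9 ± 18.1 CPM in wild-type cells without and with IFNγ and at 6.28 ± 2.00 and 74.7 ± 15.5 CPM in knockout cells, a difference of 3.58 ± 0.40 log2 (edgeR adjusted p = 4.9e-05). C1qb differed by 3.34 ± 0.51 log2, Batf2 by 3.36 ± 0.44, the chemokine Ccl12 by 3.72 ± 0.62 and Cbr2 by 4.199 ± 0.670, and these 4 were the named genes whose call held in all 31 alternative settings. H2-Aa and Ighm differed by 6.69 ± 1.61 and 4.60 ± 0.77 log2, where H2-Aa had no read in knockout vehicle libraries, so its fitted value depends on the prior count. More negative responses in knockout cells were those of Olfm4 (−7.18 ± 1.61 log2), Mmp12 (−4.51 ± 0.77), the sphingosine phosphatase Sgpp2 (−3.46 ± 0.70), Arl4a (−3.09 ± 0.64) and Arc (−3.00 ± 0.66). Olfm4 ran from −9.35 to −4.00 log2 over the settings, Mmp12 from −6.35 to −1.35, Arc from −4.13 to −1.27 and H2-Aa from 4.09 to 7.22.

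Camera called 6 of 31 lists for this difference, and none with an estimated correlation (1 at an unadjusted p under 0.05, and 1 by fry). Cell cycle genes had the more positive response in 18 of 42 and the more negative in none (26 and none adjusted over the list alone), with a median of 1.02 log2 and 1.01, 1.76 and 1.34 by batch (adjusted p = 1.8e-19, and 0.76 with an estimated correlation), Aurka at 1.80 ± 0.19 and Tpx2 at 1.16 ± 0.16 log2. Malat1 with IFNγ is given above (in batch 1 under vehicle 64.4 to 84.0 CPM in wild-type and 51.4 to 72.4 CPM in knockout cells). A share of RNA quality in this difference was not tested. Cholesterol synthesis genes were more positive in 8 of 22 (9 adjusted over the list alone; adjusted p = 0.86 with an estimated correlation), Insig1 at 2.23 and Fdps at 1.78 log2, but their median of 0.53 was 1.08 in batch 1 and −0.23 and −0.28 in batches 2 and 3. Scd2, counted with cholesterol efflux genes, differed by 2.18 log2. Phagocytosis genes were more positive in 8 of 26 and more negative in 2 (11 and 4 adjusted over the list alone; adjusted p = 0.90 with an estimated correlation), the sialic acid receptor Siglec1 at 2.62 and Cd300lf and Fcgr2b at −1.53 and −1.35 log2, with list medians of 0.94, −0.55 and 1.01 by batch. Antiviral genes were more positive in 3 of 31 (the same adjusted over the list alone), Dhx58 at 1.28 log2, with medians of 0.61, 0.16 and 0.07 by batch, and ribosomal protein genes in 7 of 29 (19 adjusted over the list alone), Rps6 at 0.96 log2, with medians of 0.58, 0.49 and 0.37. Matrix genes were more negative in 3 of 25 and more positive in 1 (3 and 2 adjusted over the list alone), the urokinase Plau at −1.97 log2, with medians of −0.58, −0.79 and 0.45, and the list lost its call in 15 of 31 settings. For antiviral, ribosomal protein and matrix genes adjusted p was 0.86 with an estimated correlation.

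GTPases, whose rise was the strongest of any list in both lines, had no member with a called difference (median −0.03 and mean 0.20 log2). Cd274, Lgals3, Rhoc, Rgs1, Cd14, Hmox1 and Vegfa had a more negative response in knockout cells by 1.14 (Lgals3) to 2.26 log2 (Rgs1), as had the receptors C3ar1 (−1.51 log2) and S1pr2 (−1.15) and the kinase Jak1 (−1.10), and Spp1 a more positive one (1.69). Of the panel fixed beforehand, Cd74 (−1.77 ± 0.39 log2) and Cxcr4 (−1.16 ± 0.29) had a more negative and Aif1 (1.73 ± 0.38), P2ry12 (1.54 ± 0.40) and Rgs10 (0.84 ± 0.24, adjusted p = 0.044) a more positive response. Cxcr4 rose in wild-type and fell in knockout cells, from 20.4 ± 10.4 to 27.5 ± 4.2 and from 17.7 ± 9.0 to 11.1 ± 2.4 CPM. Other panel genes did not pass, with Ptgs2 at −1.34 ± 0.40 (adjusted p = 0.052), Cx3cr1 at 1.63 ± 0.53 (0.073), Ccl2 at 1.10 ± 0.42 (0.13), Itgam at −0.60 ± 0.23 (0.13), Cxcl10 at 0.52 ± 0.41 (0.51), Ccl5 at 0.36 ± 0.36 (0.62), Il6 at 0.96 ± 1.06 (0.65), Nos2 at 0.33 ± 0.48 (0.74), Il1b at 0.33 ± 0.73 (0.85), Tnf at 0.24 ± 0.61 (0.87) and Stim2 at −0.01 ± 0.20 log2 (0.99). The count of 894 moved to 1448 without the batch 2 knockout IFNγ library and to 121 in batches 2 and 3 alone, and 35 of the 39 named genes past the threshold lost their call in at least 1 setting, Rgs10 in 18 and Jak1 in 11 of 31.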

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

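Every test in this part that sets an explanation against a pattern was chosen after the pattern was seen. So were the splits that exchange samples only within a batch. The other splits and the difference of the IFNγ responses were planned.

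Single libraries stood apart from the other 4 of their group in 13 of 72 group measures, by the gap to the nearest library over the group's range (above 0.71), and no count expected by chance is given, since 3 libraries of each group share batch 1 and the 5 are not exchangeable. The wild-type vehicle library of batch 2 had 0.871% of counts in mitochondrial genes (others at most 0.380%), and that of batch 3 had Mmp9 at 173.6 CPM (at most 55.1). In wild-type cells with IFNγ, the batch 2 library had Rgs10 at 49.97 CPM (at most 28.7) and C1qb at 3623 CPM (at most 1537). Among knockout vehicle libraries, batch 2 had the nuclear RNA Malat1 at 133.7 CPM (at most 72.4) and batch 3 Mmp9 at 3.72 CPM (at most 1.24). Itga9 was read in a single knockout library, replicate 3 with IFNγ, at 0.214 CPM, and with the other 4 at 0 any read passes this limit. Mmp9 stood at 19.31 CPM in the batch 3 knockout library with IFNγ (at most 2.87). Batches 2 and 3 held 12 of these 13 values. A gap to a single library misses what 2 libraries share: Malat1 stood at 955 CPM or more in all 4 IFNγ libraries of batches 2 and 3 and at 386 CPM or less in all others, and the share of this in the IFNγ changes was not tested.

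Of these values, 5 belonged to the knockout IFNγ library of batch 2. It had Rgs10 at 50.52 CPM, the nuclear RNAs Neat1 at 2186 CPM (others of its group at most 507, but 1601 and 961 in the wild-type IFNγ libraries of batches 2 and 3) and Xist at 1966 CPM (at most 440), and no read for 5.15% of tested genes (at most 1.88%). Its ratio of genes at 0 to genes with 1 to 5 reads was 1.95, where the highest other library of all groups had 0.681. That is consistent with few distinct molecules behind its reads, which raises the noise of every value from it. Against a wrong label or a large share of wild-type RNA, 8 genes chosen without batch 2, read in all wild-type and near 0 in all knockout libraries of batches 1 and 3, together had 325 reads in the wild-type IFNγ library of batch 2 and 0% of that level here, and a small share stays open. No biological explanation was tested, since no group sets this library apart.

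The response to IFNγ differed between the lines for 55 of the genes named for either response or for their difference, 29 with a more positive and 26 with a more negative response in knockout cells, by the interaction term. More positive, in log2, were H2-Aa 6.69, Ighm 4.60, Cbr2 4.199, Ccl12 3.72, Ifitm3 3.58, Batf2 3.36, C1qb 3.34, Siglec1 2.62, Insig1 2.23, Scd2 2.18, Aurka 1.80, Fdps 1.78, Aif1 1.73, Spp1 1.69, Cd36 1.59, Acat2 1.57, P2ry12 1.54, Mrc1 1.37, Dhx58 1.28, Evl 1.22, Itga4 1.21, Cyp51 1.202, Tpx2 1.16, Arhgef6 1.006, Rps6 0.96, Lyz2 0.93, Bub1b 0.85, Rgs10 0.84 and Rps4x 0.65. More negative were Olfm4 −7.18, Mmp12 −4.51, Sgpp2 −3.46, Mmp13 −3.23, Arl4a −3.09, Arc −3.003, Cd300e −2.503, Upp1 −2.28, Rgs1 −2.26, Plau −1.97, Cd74 −1.77, Cd274 −1.63, S1pr1 −1.61, Rhoc −1.54, Cd300lf −1.53, C3ar1 −1.51, Cd14 −1.45, Fcgr2b −1.35, Tapbpl −1.34, Vegfa −1.21, Hmox1 −1.21, Ccl9 −1.203, Cxcr4 −1.16, S1pr2 −1.15, Lgals3 −1.14 and Jak1 −1.10. Lists that differed, by their median, were cell cycle 1.02, ribosomal protein 0.56, cholesterol synthesis 0.53, phagocytosis 0.48, antiviral 0.32 and matrix genes −0.51. These are camera calls at the preset correlation: with an estimated one adjusted p was 0.76 to 0.90, no list passed an exact permutation test of list means, and the medians of cholesterol synthesis, phagocytosis and matrix genes changed sign between batches. Each gene was called at an adjusted p under 0.05 in edgeR's quasi-likelihood test.

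How the number of genes whose response differed ranked among splits of the samples depended on the splits allowed. Of 100 splits of the 10 paired responses, the real one included, 5 gave at least as many genes as the real 894, the highest 1119. That highest split exchanged the wild-type response of batch 2 with the knockout response of batch 3. A pair of the other splits put 5 of the 6 batch 1 responses on one side (965 and 1077 genes), and another put all 4 responses of batches 2 and 3 with 1 of batch 1 (1076 genes), so these 3 followed batch. Each of these 4 splits exchanged responses between batches. Of the 40 splits that exchange responses only within a batch, 1, the real one, gave as many genes, and the highest other gave 650, but this set was chosen after the results were seen. Within batch 1 alone the real comparison called 7096 genes and in batches 2 and 3 alone 121. For the other comparisons 1 of 100 splits, the real one, gave as many genes: 8101 against 2538 in the highest other split for IFNγ in wild-type cells, 5937 against 19 in knockout cells, 3753 against 636 for the knockout under vehicle and 5363 against 2848 under IFNγ. The same held for the 40 splits within batches. Mixed splits leave a difference between groups in the residual, and the median of the others among the 100 was 0 genes in each comparison. Libraries of different batches are also not exchangeable, so these ranks do not exclude chance. Counts of lists called by camera were no higher than in many other splits: 29, 19, 36, 48 and 87 of 100 splits gave as many lists as the real 17, 18, 13, 12 and 6, up to 21, 19, 20, 20 and 20. Within batches 19, 11, 11, 22 and 26 of the 40 splits did. Mixed splits can keep part of the real difference, and camera called lists in splits without a called gene. These counts thus cannot say whether the list calls arose by chance. By an exact permutation test of list means per library, adjusted over 31 lists, 21, 19, 20, 6 and 0 lists passed in the 5 comparisons.

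The smaller fall of cell cycle genes in knockout cells was weighed against technical explanations. A single batch as its source is argued against by the medians within batches, the lowest of which was 1.01 log2. Scaling is argued against by the lower of the medians under plain totals and RLE size factors, 0.982 log2. RNA quality was not tested as an explanation. In batch 1 the IFNγ libraries held Malat1 at 355 to 386 CPM in wild-type and 55.9 to 62.7 CPM in knockout cells. The 10 largest genes held 7.60% to 7.86% and 4.81% to 4.92% of their counts. In batches 2 and 3 Malat1 stood at 1514 and 955 CPM in wild-type and 1446 and 1004 CPM in knockout IFNγ libraries. Chance and the lines cannot be told apart for this list, since 5 responses a side gave an exact permutation adjusted p of 0.295, and exchanges within batches gave 0.155 (unadjusted 0.025, the smallest that 80 arrangements can give). A difference of the knockout line in growth under IFNγ stays a hypothesis, because no growth was measured in the counts.

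The difference between the lines shared by neighbouring genes was weighed in the same way. GC content and transcript length as the cause are argued against by a lag-50 correlation of 0.168 after both trends were taken out, above the highest shuffled value of 0.036. A batch or treatment effect is argued against by block medians that correlated across batch and treatment at 0.823 or more. Stretches of the genome at another copy number in the knockout line are a candidate explanation, with 52 blocks shifted the same way under both treatments where shuffled orders gave at most 1, and DNA was not analysed here. After removal of the shared shift 2379 genes were called under vehicle. They cannot show whether copy number was the whole cause, since shorter stretches and effects on other genes stay in. For lack of a second knockout line, a part of the change made at RGS10 or of the separate history of the lines stays open.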

How the results depend on the processing

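Treatment-specific batch terms, plain library totals, batches 1 and 3 alone and the neighbour-shift removal were chosen after seeing the data, the other settings before. All were run. The cause of the changes below was not tested.

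Counts of called genes moved with the batches used, where the number of libraries changed too. Batches 2 and 3 alone, with 1 library of each group per batch, gave 5101 genes for IFNγ in wild-type cells, 847 and 1920 for the knockout under vehicle and IFNγ, and 121 for the difference of the responses, 53 of them among the 894. Batch 1 alone gave 8072 and 9580 genes for the knockout under vehicle and IFNγ and 7096 for the difference of the responses, with 10 lists in place of 6. Without a batch term 3897 genes were called for IFNγ in knockout cells, 2318 for the knockout under vehicle and 138 for the difference. Batches 1 and 3 alone gave 1906 genes for the difference, treatment-specific batch terms 2360, DESeq2 1480, plain library totals 537 and the replicate number as a block 530. With only the groups compared 6224 genes were called for the knockout under vehicle. With the neighbour shift removed 2379 were, 1949 of them among the 3753. An adjusted p under 0.01 also gave 2379 genes there, and 259 for the difference of the responses. Asking for at least 1 log2 left 4143, 2320, 1488, 2119 and 473 genes in the 5 comparisons.

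Leaving out 1 library moved the count for the difference of the responses between 542 and 1448. It was 542, 543 and 575 without KO_vehicle replicates 1, 2 and 3, 572, 552 and 553 without KO_IFNg replicates 1, 2 and 3, and 1448 and 1437 without KO_IFNg replicates 4 and 5. With an estimated correlation camera called 1, 4, 0, 0 and 0 lists in place of 17, 18, 13, 12 and 6, and 9, 10, 3, 4 and 1 at an unadjusted p under 0.05. By fry 24, 23, 18, 18 and 1 lists passed. Pearson r of the IFNγ responses was 0.69 in batch 1 and 0.73 in batches 2 and 3, against 0.82.

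The fall of Rgs10 with IFNγ in knockout cells, which did not pass the test, passed in batch 1 alone (−0.56 log2), without KO_vehicle replicate 4 (−0.46) or KO_IFNg replicate 4 (−0.54), with treatment-specific batch terms (−0.34), with plain totals (−0.46) and in batches 1 and 3 (−0.57). Rgs10 under IFNγ did not differ between the lines by the test, but did in batch 1 alone (−0.28 log2), with treatment-specific batch terms (−0.35), in batches 1 and 3 (−0.44) and with the neighbour shift removed (−0.50). Leaving out 1 library gave values from −0.56 (without KO_IFNg replicate 4) to −0.24 (without KO_IFNg replicate 5).

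Changes of sign were mostly of values that did not pass the test. In batches 2 and 3 alone, log2 changes of the other sign were those of Cxcr4 with IFNγ in wild-type cells (−0.12), Rgs10 (0.057) and P2ry12 (−0.50) with IFNγ in knockout cells, Stim2 (−0.082), Cxcl10 (0.67) and Cx3cr1 (0.31) for the knockout under vehicle, Cx3cr1 (−0.97) and mt-Cytb (0.31) for the knockout under IFNγ, and Cxcl10 (−0.37), Stim2 (0.11), Cx3cr1 (−1.28) and Tnf (−0.15) for the difference of the responses. The cholesterol synthesis list also turned there, with a camera adjusted p of 0.17. In batch 1 alone they were Il1b with IFNγ in knockout cells (−0.26), Itgam (0.026), Tnf (−0.070) and Cd74 (0.050) for the knockout under vehicle, Ccl2 (−0.082) and Tnf (−0.12) under IFNγ, and Il1b (−1.41), Il6 (−0.20), Nos2 (−0.96) and Tnf (−0.046) for the difference.

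P2ry12 with IFNγ in knockout cells, at 0.01 log2, turned to −0.015 without a filter, −0.030 with treatment-specific batch terms and −0.13 with plain totals. For the difference of the responses, Stim2 turned to 0.0047 without a filter, 0.079 with plain totals and 0.015 in batches 1 and 3, Il1b to −0.042 and Tnf to −0.11 with treatment-specific batch terms, and Tnf to −0.20 with limma-voom. Cxcl10 for the knockout under IFNγ turned to −0.15 in batches 1 and 3. Removing the neighbour shift turned Stim2 (−0.15), Rac1 (−0.0096), Abca1 (−0.019), Cx3cr1 (0.65) and Tnf (−0.065) for the knockout under vehicle and Stim2 (−0.16) and Cdc42 (0.090) under IFNγ. By construction this removal took out what 50 neighbouring genes shared.

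Leaving out 1 library in turn moved P2ry12 with IFNγ in knockout cells between −0.12 and 0.19. For the knockout under vehicle it moved Il6 between −0.24 and 0.73, Itgam between −0.23 and 0.053 and Tnf between −0.14 and 0.35. For the knockout under IFNγ it moved Stim2 between −0.030 and 0.24, Cxcl10 between −0.074 and 0.58, Ccl2 between −0.058 and 0.41 and Tnf between −0.16 and 0.67. For the difference of the responses it moved Il1b between −0.69 and 0.65, Stim2 between −0.16 and 0.13, Il6 between −0.021 and 1.49, Nos2 between −0.051 and 0.51 and Tnf between −0.34 and 0.51. The ends for the knockout under IFNγ below 0 came without KO_IFNg replicate 4 for Cxcl10, Ccl2 and Tnf and without KO_IFNg replicate 5 for Stim2.

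Among the named genes, calls were lost or turned sign 77 times in batches 2 and 3 alone, 74 times on leaving out a library, 40 times without a batch term, 13 times with the neighbour shift removed, 8 times with the replicate block, 6 times with plain totals and at most 4 times in any other setting. Among the lists this came to 61 times with an estimated correlation, 19 on leaving out a library, 10 in batches 2 and 3 alone, 5 by fry and at most 3 in any other setting. Calls of named genes were gained 13 times on leaving out a library, 12 times in batch 1 alone, 7 times with treatment-specific batch terms, 6 times without a filter and at most 3 times in any other setting.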

Other observations

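The tests in this part on neighbouring lost genes were chosen after the result was seen, and the gene lists were fixed before the data were examined.

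Lists that camera did not call, and that are not described above, moved little or in both directions. Glycolysis and hypoxia genes fell in 12 and rose in 3 of 27 with IFNγ in wild-type cells (camera adjusted p = 0.12) and fell in 10 and rose in 4 in knockout cells (adjusted p = 0.089). Under IFNγ, 7 were higher and 4 lower in the knockout line. Genes of LXR and cholesterol efflux rose in 7 and fell in 5 of 13 in wild-type and rose in 3 and fell in 5 in knockout cells, and G protein genes rose in 6 and fell in 7 of 27 and rose in 4 and fell in 4. Store-operated calcium entry genes rose in 5 and fell in 10 of 20 in wild-type and rose in 5 and fell in 7 in knockout cells. Antiviral genes rose in 14 and fell in 6 of 31 in wild-type cells (adjusted p = 0.16). Mitochondrially encoded genes had a median of −1.08 log2 for the knockout under IFNγ, with 6 of 10 lower, but −1.86, 0.79 and −0.06 in batches 1, 2 and 3. Of the 8 genes listed as neighbours of Rgs10, whose place was not checked, 1 was higher and 2 lower for the knockout under IFNγ. Their median lay between −0.03 and 0.03 log2 in the 4 comparisons of groups. Their list mean, however, differed by −0.18 log2 for the knockout under vehicle (exact permutation adjusted p = 0.037). Medians there were −0.13, 0.17 and −0.27 log2 in batches 1, 2 and 3.

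Median, mean and camera direction of a list differed in sign only for lists that were not called. Among lists tested by camera, the widest gaps between a median and a mean of opposite sign were those of homeostatic markers with IFNγ in wild-type cells (median 0.04, mean −0.73 log2), class II genes in the difference of the responses (median −0.25, mean 0.91) and cholesterol efflux genes for the knockout under vehicle (median 0.02, mean −0.46).

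Markers of other cell types were few and mostly low. Of 3 neuronal markers all were lower in the knockout line under both treatments, and 3 of 3 lymphocyte markers of the fixed list were lower under IFNγ, while the immunoglobulin gene Ighm, not in that list, was 226-fold higher. Kdr, an endothelial marker, was the exception in level, at 319 CPM in knockout vehicle libraries. The wells held a single line, so these are differences between the lines, and no other cell type was tested as their source. Of 2 astrocyte markers 1 rose and 1 fell with IFNγ in wild-type cells, and of 3 oligodendrocyte markers 1 fell.

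Most called differences between the lines were small: 60.4% under vehicle and 60.5% under IFNγ were under 1 log2. At the other end, 264 and 202 genes differed by at least 4 log2, beyond the largest neighbour shifts of 1.12 and −0.86 log2 for the line.

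Some genes were off in 1 line. Afap1, Ccl24, Cmklr1, Cth, Gm53, Hoxb9, Lin28b and Pxylp1 were read in all wild-type and near 0 in all knockout libraries of batches 1 and 3, from which they were chosen, and Gm15398 and Gm6526 the other way round. Loss of stretches of DNA that hold several expressed genes may be the cause of the first set. Of these 8 genes, 25% had an adjacent tested gene that was also lost, which equalled the highest of 1000 shuffles. The shuffles test whether lost genes lie together, not how they were lost. Deletion and silencing thus cannot be told apart by them, and the genes are few. Counts of reads along each gene, a second knockout line and a measure of DNA copy number would part these explanations.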
